A study of Mus musculus with 58 samples.

How the data were processed

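RNA of normal liver and liver tumors was measured on 58 arrays, 29 of each tissue. Per the labels' protocols, total RNA was extracted with the miRNeasy kit and the RNA was amplified and labelled with biotin using the kits Affymetrix recommends for whole-transcript arrays, and the probe table names the array as the Mouse Gene 2.0 ST type. The authors processed the arrays with Affymetrix Expression Console, per the submitters' processing notes, and its version, algorithm and genome build are not given in the sources used here. The deposited values are on a log2 scale, one per transcript cluster and array, from 2.91 to 14.08. Their array medians, between 6.72 and 7.15, lie close together, which is what values brought to a common scale by the authors look like, but the method is not given in the sources used here. Scanner output was not used here, so background, detection and hybridization date could not be examined, and a dim gene has no stated detection limit. Array precision depends on the number of arrays.

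Groups were taken from the tissue label of each sample, and sex from the gender label, which is missing for 1 tumor. Replicate numbers only name arrays. Animals were read from the titles, 39 in all. The 18 animals that gave both tissues are pairs because the titles name the same animal. As a check, deviations from the group means correlated with a median of 0.241 between both arrays of an animal (range -0.196 to 0.539, above 0.1 in 15 of 18 pairs) against -0.016 between different animals. The best match of a normal liver was its own tumor in 2 of 18 cases. Titles with differing spellings were kept apart as different animals, and a looser reading was tried. Normal livers 26 and 27 bear one animal title and were kept apart by their +/- and -/- marks, whereas tumors 22 and 26, of which only tumor 22 is marked, were taken as 1 animal. No 2 arrays were identical, and pairwise correlations ran from 0.793 to 0.990. The lowest mean correlation with the other arrays was that of tumor 9, at 0.839.

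Clusters were named through the platform table given with the values. Of 41345 clusters 23521 had 1 gene symbol, 1814 had several and 16010 had none there. Genes were named only from clusters with 1 symbol, and where a gene had several clusters (1082 genes) the one with the highest mean was used. Gene order at one locus came from the table of assembly GRCm38.p6, in which all 44 measured members were found, and no coordinate from it is printed.

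Tests were made with limma 3.58.1 and statmod 1.5.0 in R 4.3.3, and figures with matplotlib 3.10.9 in Python 3.11.15. Tumors were compared with normal liver by lmFit with the animal as a random block through duplicateCorrelation (block correlation 0.145), followed by eBayes with a trend and Benjamini-Hochberg adjustment over 22180 genes. Calls needed an adjusted p under 0.05 and, for the counts, a log2 change of at least 1. Sex contrasts and their interaction came from one fit of 4 groups over 57 arrays (block correlation 0.148). The -/- and +/- marks were compared in 9 normal male livers without a block, since marked tumors mix labelled sexes. Gene lists, including markers of other liver cell types, were tested with camera on values and design made independent with the block correlation, at a preset correlation of 0.01 and with an estimated one. Of the 20 lists that passed with the preset correlation, 0 passed with the estimated one. Locus members were counted in tumors above the highest normal liver, and their 18 paired differences were tested by an exact sign-flip test over 262144 flips, for which the smallest possible p is 7.6e-06.

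The tests were tried on simulated data with known changes in 100 genes per size among 22180. A log2 change of 0.5 between tumors and normal liver was recovered in 90% of changed genes and one of 1 in 99%. For the difference in tumor change by sex, 91% were recovered at 1 and 100% at 2, and for sex in normal liver 95% and 100%. For the genotype marks 71% were recovered at 1 and 98% at 2. The simulated genes varied independently of each other, with the spread of the normal livers and with correct labels. In the data some genes, Rian among them, varied more in tumors, and 7 arrays went against the gender label. Recovery in the data can therefore be lower than these percentages, above all for the sex contrasts.

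The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes every measured member of the Dlk1-Dio3 locus, with small RNAs given as counts, and the 10 largest changes each way with an adjusted p under 0.05 and the same sign in at least 15 of 18 pairs. It also takes up to 3 members of smallest adjusted p and the member of largest change from each list, Mmut and Afp. For sex it takes Xist, the Y-linked genes, the 5 largest differences each way in normal liver and up to 3 members of each sex-biased list, and for the marks the 5 smallest p each way. Members outside it, such as Gpc3, Axin2, Srebf1, Cdkn1a and Trim71, and the few members named as exceptions to a list's direction, were named after their values were seen. Alternatives covered the block, the subset of arrays, the reading of titles, another normalization, centring, a filter on dim genes, the choice of cluster, array weights, a sex covariate and the trend. After seeing the data, fits without each animal, without the 7 arrays whose sex-chromosome transcripts went against the gender label, without tumor 9 and without the 3 arrays whose titles share the animal number of normal liver 27 were added. So were the estimated correlation of the lists in 3 of the alternatives, the sex-biased lists adjusted alone for the interaction, and the Rian counts by label without the 4 tumors against it. Genes measured only by clusters with several symbols were not analysed here.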

Results

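Gene expression was measured on arrays in normal liver and liver tumors of adult mice that had been injected with adeno-associated virus (AAV), a vector used for gene transfer, as newborns. The design asks whether insertion of the vector into the mouse genome contributed to hepatocellular carcinoma. The data comprise 58 arrays, 29 of normal liver and 29 of tumors. The titles name 39 animals, of which 18 gave one array of each tissue and 1 gave 2 tumors. The mice were of a mixed background of inbred strains. The labels give neither a vector dose nor, for most arrays, the vector used, so tumors were compared with normal liver and not between vectors. Each array gave one log2 value for each of 41345 transcript clusters, and the array medians lay between 6.72 and 7.15. The number of arrays, not a count of molecules, limits the precision. Of the clusters, 23521 carried a single gene symbol, and the 22180 genes they represent were tested. Positions on the genome are not given, since the files name no build.

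Liver tumors differed from normal liver in genes of the fetal liver, of cell division and of the mature hepatocyte. With an adjusted p under 0.05 and a change of at least 1 on the log2 scale, 229 genes were higher and 210 were lower in tumors. The largest rise among genes that moved the same way in at least 15 of the 18 pairs was that of Cyp11a1 (transcript cluster 17517831), which encodes the enzyme that begins steroid hormone synthesis. Its log2 value was 6.70 ± 0.92 (SD, n = 29) in normal liver and 10.26 ± 1.96 (SD, n = 29) in tumors, an 11.7-fold difference (log2 change 3.55, SE 0.37, limma adjusted p = 5.2e-11) that was seen in 16 of 18 pairs. The largest fall was that of Slco1b2 (transcript cluster 17464080), a hepatocyte uptake transporter for bile acids and drugs. It went from 11.46 ± 1.16 to 7.97 ± 2.10 (SD, n = 29 each), an 11.4-fold decrease (log2 change -3.52, SE 0.41, adjusted p = 1.1e-09) in 17 of 18 pairs. Afp, the fetal albumin relative used as a marker of liver cancer, rose 3.57-fold (log2 change 1.84, SE 0.27, adjusted p = 2.1e-07) and was higher in 17 of 18 pairs.

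The other 9 of the 10 largest rises were those of Serpinb9e, Glod5, Slpi, Gucy2c, Rgs2, Apela, Muc13, Slc7a11 and Wfdc15b. Serpinb9e rose 10.6-fold and Apela, which encodes a peptide ligand of the apelin receptor, rose 6.52-fold, both in 18 of 18 pairs. Slpi, a secreted protease inhibitor, rose 7.96-fold and Gucy2c, an intestinal guanylate cyclase receptor, rose 7.35-fold. The mucin gene Muc13 rose 6.41-fold, and Slc7a11, which encodes the cystine-glutamate exchanger, rose 6.15-fold with the widest error of the 10 (log2 change 2.62, SE 0.47). The other 9 of the 10 largest falls were Cyp2c38, Rgn, Cyp2c37, Cyp2c50, Ces1g, Cyp2c54, Nr1i3, Cyp2e1 and Pon1. Cyp2c38 fell by 3.31, Rgn by 3.00, and Nr1i3, the nuclear receptor CAR that regulates drug metabolism, fell by 2.78 on the log2 scale. Cyp2e1 fell by 2.66 and was lower in tumors in 18 of 18 pairs. The Cyp2c genes have closely similar sequences, so the array may not keep them apart. By adjusted p alone, without a limit on the size of the change, 3964 genes were higher and 3166 lower. With each array centred on its median these became 4689 and 1727, so the split between smaller rises and falls depends on the scaling. Among the 11 normal livers and 11 tumors of animals without a pair, 77 of the named genes lost their call, Rgn (log2 change -2.66, adjusted p = 0.0501) and Pon1 (-2.15, adjusted p = 0.0634, against -2.62 with all arrays) among the 20 above.

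All 37 measured genes of the proliferation list rose, and 37 rose when adjusted over the list alone. The set test camera, which compares a list with the other genes, gave adjusted p = 1.4e-27 with a preset correlation and adjusted p = 0.137 with an estimated correlation. Rrm1, a subunit of ribonucleotide reductase, rose 2.80-fold (log2 change 1.48, SE 0.14), Mcm2 of the replicative helicase 1.81-fold and Stmn1 1.61-fold. Of 29 genes of the list for fetal liver and hepatocellular carcinoma, 21 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 7.2e-10, adjusted p = 0.110 with an estimated correlation). Cd24a rose 5.07-fold, the transcription factor gene Sox4 4.34-fold and Robo1 2.81-fold. Gpc3, another carcinoma marker on that list, was not called (log2 change 0.07, SE 0.13, adjusted p = 0.718). Peg3 and Trim71 were the 2 members that fell. Among 14 genes of glycolysis, 11 rose and none fell, with 11 adjusted over the list alone (camera adjusted p = 4.4e-08, adjusted p = 0.205 with an estimated correlation). Pfkp, the platelet isoform of phosphofructokinase, rose by 2.17 on the log2 scale (SE 0.18) in 18 of 18 pairs, and the glucose transporter gene Slc2a1 rose 3.00-fold.

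Genes of the hepatocytes around the central vein, many of them targets of Wnt signalling, fell in tumors. Of 21 measured members 18 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 1.8e-12, adjusted p = 0.110 with an estimated correlation). Glul, glutamine synthetase, fell by 1.62 (SE 0.19) and Rnf43, a feedback inhibitor of Wnt signalling, fell by 1.43 (SE 0.16) on the log2 scale, each in 17 of 18 pairs. Slc1a4 and Oat were the members that rose, and Axin2 was not called (log2 change -0.04, SE 0.06, adjusted p = 0.662). The periportal list gave 4 rises and 1 fall among 16 members, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.62 with an estimated correlation). Etnppl rose 5.88-fold and Aldh1b1 4.20-fold, whereas Pigr, the transporter of IgA into bile, fell by 1.68. Without the 7 arrays described with the gender labels below, the adjusted p of the periportal list was 0.0864, and among brighter genes only it was 0.211.

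Genes of drug, bile acid and lipid metabolism were lower in tumors. Of 48 cytochrome P450 genes 32 fell and 4 rose, the same counts as adjusted over the list alone (camera adjusted p = 2.6e-11, adjusted p = 0.284 with an estimated correlation). Cyp2d40 was lower in 18 of 18 pairs, and fell by 1.05 on the log2 scale. The members that rose were Cyp2b10, Cyp2a5, Cyp17a1 and Cyp2g1, the first by 1.87. Of 18 bile acid genes 13 fell and none rose, 13 also when adjusted over the list alone (camera adjusted p = 1.5e-07, adjusted p = 0.284 with an estimated correlation). Besides Slco1b2, the bile acid importer gene Slc10a1 fell by 1.97 (SE 0.27) and Cyp27a1 by 1.14. Among 19 genes of lipogenesis 12 fell, or 14 adjusted over the list alone (camera adjusted p = 2.3e-07, adjusted p = 0.284 with an estimated correlation). Thrsp fell by 2.21 and Pnpla3 by 1.57, while Srebf1 was not called (log2 change -0.10, SE 0.14, adjusted p = 0.620). Of 19 genes of cholesterol synthesis 10 fell, or 11 adjusted over the list alone (camera adjusted p = 0.00023, adjusted p = 0.541 with an estimated correlation), among them Cyp51, which fell by 1.06, and Stard4, by 0.99. In fatty acid oxidation 3 of 19 genes fell, 3 also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.322). Those were Eci2, Crot and Acaa2, with log2 changes of -0.49, -0.49 and -0.34. Each lost its call among the 18 pairs alone with the animal as a fixed block (adjusted p between 0.0719 and 0.138), where the changes were -0.46, -0.45 and -0.39. Acaa2 also lost it with arrays centred on the median (-0.29, adjusted p = 0.0815). Acaa1b had the largest change of the list and was not called with all arrays (-0.60, SE 0.25, adjusted p = 0.0584). It was called as lower with quantile normalization (adjusted p = 0.0415) and among brighter genes only (adjusted p = 0.0414). It was also called among the arrays of animals without a pair (-0.91, adjusted p = 0.0304).

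Secreted liver proteins fell as well. Of 30 plasma protein genes 14 fell, or 19 adjusted over the list alone (camera adjusted p = 3.4e-06, adjusted p = 0.541 with an estimated correlation). Apoa1 was lower in 18 of 18 pairs, with a fall of 0.74, and Apoa5 fell by 1.29. Of 15 complement genes 13 fell, or 14 adjusted over the list alone (camera adjusted p = 1.2e-06, adjusted p = 0.328 with an estimated correlation), and the terminal component gene C8a fell by 1.81. Of 20 acute phase genes 9 fell and 1 rose, or 12 and 1 adjusted over the list alone (camera adjusted p = 0.00062, adjusted p = 0.541 with an estimated correlation). Saa4 fell by 2.57 and Orm3 by 1.98, the latter in 18 of 18 pairs, and the member that rose was Il1rn, the interleukin 1 receptor antagonist (log2 change 0.77, SE 0.19).

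Several stress and signalling lists rose. Of 18 targets of p53 13 rose and 2 fell, or 14 and 2 adjusted over the list alone (camera adjusted p = 1.0e-05, adjusted p = 0.284 with an estimated correlation). Btg2 rose 3.46-fold and the death receptor gene Tnfrsf10b 2.32-fold, while Cdkn1a had a change of 0.42 (SE 0.23, adjusted p = 0.154), and Fas and Perp were the members that fell. Among 19 interferon response genes 8 rose, or 11 adjusted over the list alone (camera adjusted p = 1.1e-06, adjusted p = 0.352 with an estimated correlation). The chemokine gene Cxcl10 rose 3.88-fold and Rsad2 3.69-fold, each in 17 of 18 pairs. Among 20 targets of Nrf2, the regulator of antioxidant genes, 8 rose, also adjusted over the list alone (camera adjusted p = 0.0098, adjusted p = 0.62 with an estimated correlation). Besides Slc7a11, Srxn1 rose 2.13-fold and Abcc4 2.19-fold. The Nrf2 list did not pass among brighter genes only (adjusted p = 0.169) or without the 7 arrays described below (adjusted p = 0.0515). Of 14 immediate early genes 8 rose and 1 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0076, adjusted p = 0.541 with an estimated correlation), with Nr4a1 up 1.83-fold and Zfp36 the member that fell. Among brighter genes only the adjusted p of this list was 0.0760. Btg2 had the largest change of this list too (log2 change 1.79), so the p53 and immediate early lists are not separate.

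**Figure D1:**
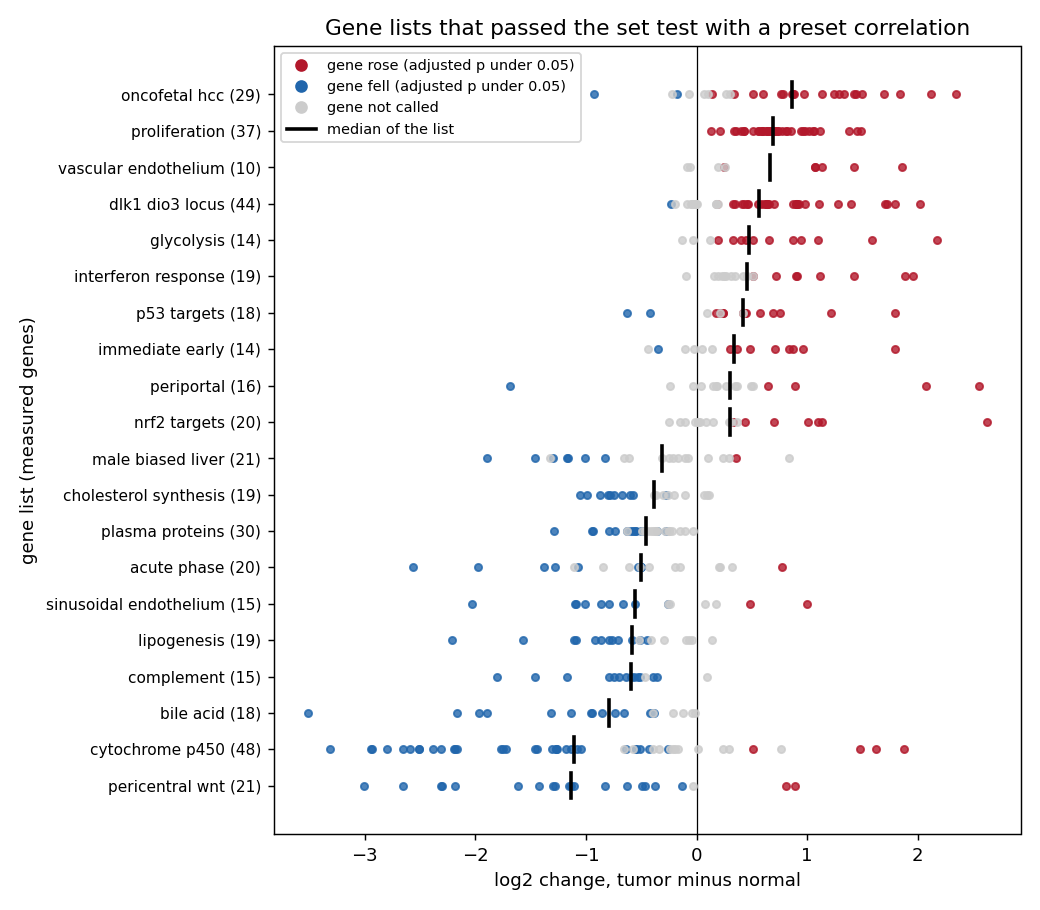
Log2 change between tumors and normal liver (x axis, tumor minus normal) for the genes of the 20 lists (y axis, with the number of measured genes) that passed camera with a preset correlation. Each dot is a gene, red where it rose, blue where it fell and grey where it was not called, and the black bar is the median of the list. All 37 proliferation genes lie right of 0, and 18 of the 21 pericentral genes are blue.

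Markers of other liver cells moved with the tissue, and in different directions. Of 15 markers of sinusoidal endothelium 9 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0010, adjusted p = 0.438 with an estimated correlation). Clec4g fell by 2.03 (SE 0.28) and Stab2 by 1.01 (SE 0.16), while Flt4 rose 2.00-fold and Pecam1 1.40-fold. Of 10 markers of other vessels 6 rose, or 7 adjusted over the list alone (camera adjusted p = 0.00017, adjusted p = 0.284 with an estimated correlation), with Esm1, a marker of sprouting endothelium, up 3.63-fold and Cd34 up 2.10-fold. Macrophage markers, not all of them particular to the resident Kupffer cells, parted, with 4 rises and 5 falls among 15, the same adjusted over the list alone (camera adjusted p = 0.131). Vsig4 fell by 2.37, Clec4f by 2.06, Timd4 by 1.20, Cd5l by 2.12 and Marco by 1.10, and Gpnmb, Cd14, Cd68 and Trem2 rose. Among the 18 pairs alone with the animal as a fixed block this list passed (adjusted p = 0.0348, adjusted p = 0.525 with an estimated correlation). Of 19 markers of stellate cells and fibroblasts 5 rose and 6 fell, or 6 and 6 adjusted over the list alone (camera adjusted p = 0.637, a list whose median was above 0 and whose mean and test were below). Ecm1 fell by 1.22 and Reln by 1.18, and the collagen gene Col1a1 rose by 1.07. Of 9 cholangiocyte markers 4 fell, also adjusted over the list alone (camera adjusted p = 0.355), which were Pkhd1, by 0.66, and by at most 0.20 Krt19, Cldn7 and Krt7. Krt19 and Cldn7 lost their calls with arrays centred on the median (-0.14 each, adjusted p = 0.152 and 0.169). Among 15 markers of T and natural killer cells 2 rose, or 1 adjusted over the list alone (camera adjusted p = 0.915, with a median below 0 and a mean and test above). These were Cd4 (1.39-fold) and Ccl5 (1.41-fold), and Ccl5 lost its call among the 18 pairs alone with the animal as a fixed block (log2 change 0.42 against 0.50, adjusted p = 0.235). Ccl5 also lost it without tumor 9 (0.38, adjusted p = 0.0556) and with quantile normalization (0.45, adjusted p = 0.0548). Among the arrays of animals without a pair neither Ccl5 (0.65, adjusted p = 0.101) nor Cd4 (0.31, adjusted p = 0.238) was called. Without tumor 9 the direction of the list was down (camera adjusted p = 0.355). No marker of B or plasma cells (9 genes, camera adjusted p = 0.972, with a median above 0 and a mean and test below), neutrophils (12 genes, camera adjusted p = 0.396) or red cells (3 genes, camera adjusted p = 0.581) was called with all arrays, over all genes or adjusted over the list alone. Without tumor 9 Ighm fell by 0.60 (adjusted p = 0.0132) and Pou2af1 by 0.28 (adjusted p = 0.0189), and the T and natural killer cell marker Cxcr6 fell by 0.29 (adjusted p = 0.00241), all 3 also called as lower with array weights, as were S100a9 (adjusted p = 0.0149) and Epb42 (adjusted p = 0.00548). In the 18 pairs with the animal as a fixed block S100a9, Elane and Retnlg were called as lower (adjusted p between 0.0168 and 0.0432). The neutrophil list passed as lower in tumors among the 18 pairs alone with the animal as a fixed block (adjusted p = 0.0134, adjusted p = 0.489 with an estimated correlation).

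Of the genes higher in male liver 7 of 21 fell and 1 rose, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.62 with an estimated correlation). Slco1a1 fell by 1.90 and C8b by 1.46, and Selenbp2 rose by 0.35. This list did not pass among the 18 pairs alone with the animal as a fixed block (adjusted p = 0.0624), with sex as a covariate (0.0700) or without tumor 9 (0.0840). Mmut, the gene of methylmalonyl-CoA mutase, was 1.66-fold lower in tumors (log2 change -0.73, SE 0.22, adjusted p = 0.0074). It was lower in 11 of 18 pairs, and among those pairs alone with the animal as a fixed block the change was -0.48 (adjusted p = 0.182). In the arrays of animals without a pair the Mmut change was -1.22 and was not called either (adjusted p = 0.0547). The -/- and +/- marks described below were given for only some arrays and were not in these fits. Among animals without a pair, a difference in genotype therefore cannot be told from one of tissue. Of 27 measured genes of propionate and branched-chain amino acid breakdown 10 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0792, and 0.00922 without tumor 9, there 0.664 with an estimated correlation), with Dbt up 1.81-fold and Mccc1 up 1.53-fold, and Pccb and Mmut the members that fell. Mouse counterparts of 5 genes that carry AAV insertions in human liver cancers were examined. Of these Ccna2 (1.93-fold), Ccne1 (1.26-fold) and Tnfsf10 (1.33-fold) rose, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.120). Ccna2 and Ccne1 are also on the proliferation list, and Tnfsf10 lost its call among the 18 pairs alone with the animal as a fixed block (log2 change 0.32 against 0.41, adjusted p = 0.15). Tert (log2 change -0.20, SE 0.13) and Kmt2b (-0.08, SE 0.07) did not pass.

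The imprinted Dlk1-Dio3 locus was examined tumor by tumor, because AAV insertions at this place in mouse liver tumors are known. Rian (transcript cluster 17278715), a long non-coding RNA expressed from the maternal copy, rose 4.06-fold on average (log2 change 2.02, SE 0.42, adjusted p = 0.00012). Normal livers had a Rian log2 value of 7.03 ± 0.92 (SD, n = 29), between 5.88 and 8.83. The highest was normal liver 27, which lay among the tumors in a score described below. The next was normal liver 28 at 8.76, a limit that would leave the count of tumors above it the same. Of the 29 tumors 14 lay above the highest normal liver, with values between 9.10 and 12.20, where chance alone puts 0.967 tumors above. The tumor was higher than its own normal liver in 16 of 18 pairs (exact two-sided sign-flip test, p = 7.6e-05, adjusted p = 0.0034 over the 44 measured members), and in 10 of the 18 the tumor exceeded every normal liver. Among the 11 normal livers and 11 tumors of animals without a pair, the Rian change was 0.92 and was not called (adjusted p = 0.422). These 14 tumors spanned 11 of 17 labelled male and 3 of 11 labelled female (two-sided Fisher's exact test, p = 0.120). Tumors 14, 15 and 28 among them carry sex-chromosome transcripts against the label, as described below, and without the 4 such tumors the counts were 9 of 15 and 2 of 9 (p = 0.105).

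The microRNA genes that follow Rian on the chromosome rose with it. By gene order in the assembly GRCm38.p6, the first of the 30 members that rose was Rian and the last Mir409, and 6 of the 36 measured members in this stretch, whose ends were set after the values were seen, did not rise. The list named 60 members and 44 were measured. Where the rise starts and ends among members that were not measured is therefore not known. Among the 39 microRNA genes 29 rose, by between 0.19 and 1.80 on the log2 scale, and in each of these between 7 and 14 tumors lay above the highest normal liver. With the limit at the mean plus 3 SD of the normal livers these numbers were 2 for Mir494, 4 for Mir539, 6 for Mir495 and 7 for Mir1188, from 7, 7, 11 and 12. Among the normal livers and tumors of animals without a pair, all 29 lost their call (adjusted p between 0.161 and 0.928, changes between 0.03 and 1.13). Mir453 (3.29-fold), Mir323 (3.25-fold) and Mir380 (log2 change 1.80, SE 0.40) were examples. Before Rian, the change of Dlk1 was smaller than its error (log2 change -0.0041, SE 0.07), although 4 tumors lay above the highest normal liver, or 2 with the limit at the mean plus 3 SD. Meg3, a long non-coding RNA of the maternal copy like Rian, was not called (log2 change -0.02, SE 0.08, adjusted p = 0.894), with 0 tumors above the highest normal liver. After Mir409, Dio3 was not called (log2 change -0.04, SE 0.06) with 0 tumors above, and Dio3os fell by 0.23 (SE 0.05, adjusted p = 0.00061). The sign-flip test called 30 members up and 1 down at an adjusted p under 0.05. Of the 325 instances in which a member other than Rian exceeded all normal livers in a tumor, all but 28 came from the tumors that did so for Rian. As a list of 44 members 30 rose and 1 fell, or 30 and 2 adjusted over the list alone (camera adjusted p = 2.8e-06, adjusted p = 0.541 with an estimated correlation). With only genes above the median brightness the list did not pass (adjusted p = 0.782). That filter takes out dim members, so this test covered another set of members. Mir376a, Mir379 and Mir380, which rose, had means of 3.34, 3.58 and 4.43 in normal liver, where the lowest array median was 6.72. Rian had 7.03, and how many members were left is not given here. Without the 7 arrays described with the gender labels below, Mir370, Mir381, Mir409, Mir494, Mir539 and Mir679 lost their calls, with changes between 0.17 and 0.55. Among the 18 pairs with the animal as a fixed block Mir370 (log2 change 0.88, adjusted p = 0.0842, against 0.65 with all arrays) and Mir409 (0.74, adjusted p = 0.0652, against 0.55) were not called, although their changes were larger. Mir370 (0.62, adjusted p = 0.0528) and Mir539 (0.18, adjusted p = 0.0834) also lost their calls without the animal as a block, and Mir539 with the looser reading of titles (0.18, adjusted p = 0.0527). Of 13 neighbouring genes 2 rose and 2 fell, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.915), with a median of 0 tumors above the highest normal liver and at most 7, in Mok, as many as in the lowest of the microRNA genes that rose. Hsp90aa1 and Wars rose by 0.41 and 0.34, and Degs2 and Wdr20 fell by 0.19 and 0.17. Wars lost its call among the 18 pairs with the animal as a fixed block (0.28, adjusted p = 0.0619) and Degs2 with quantile normalization (-0.13, adjusted p = 0.0502). The probes measured RNA from these genes in total RNA and do not tell mature microRNAs from their precursors.

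**Figure D2:**
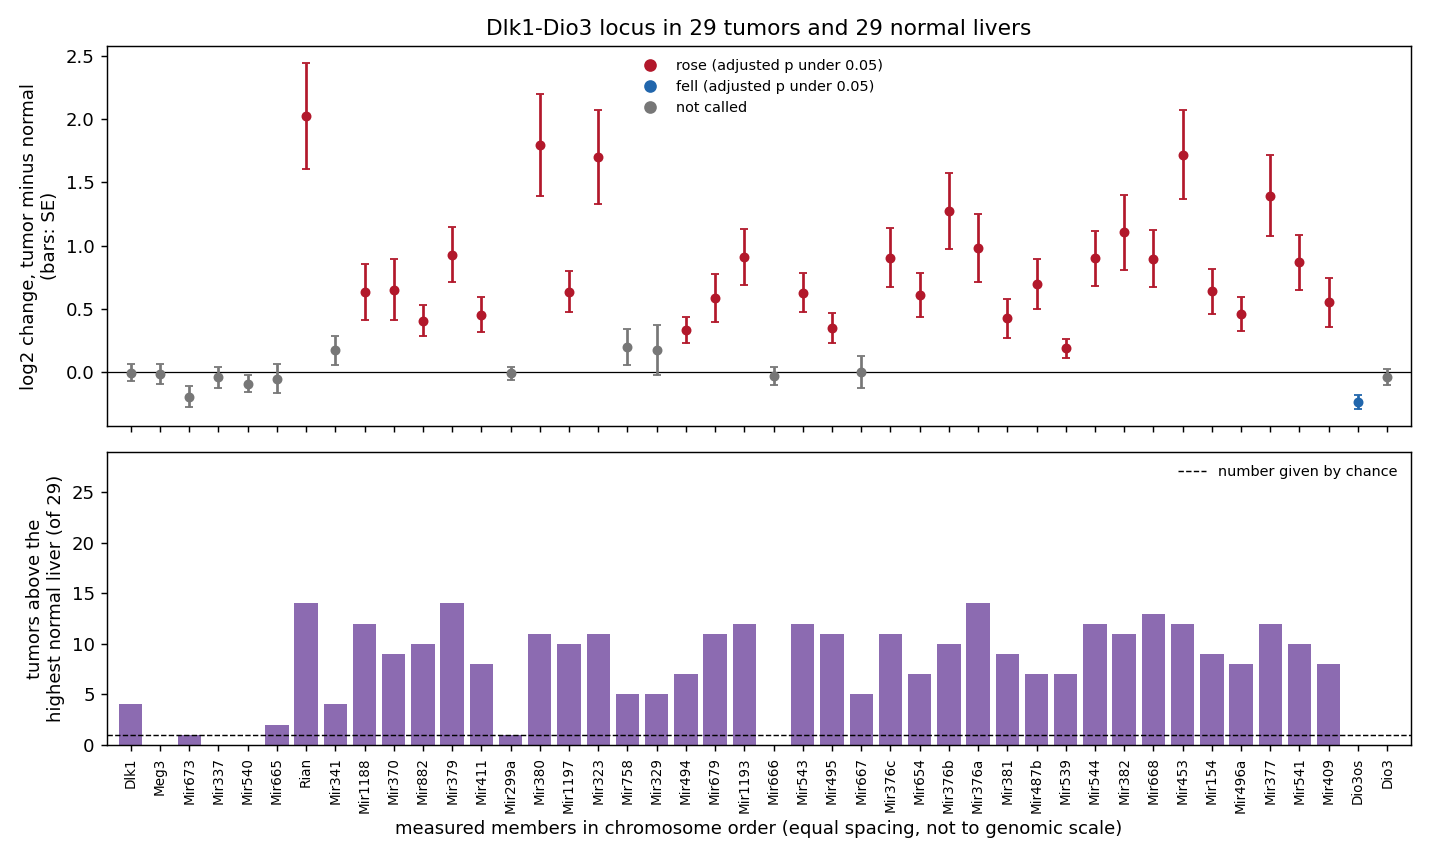
Measured members of the Dlk1-Dio3 locus in chromosome order (x axis, equally spaced). The upper panel gives the log2 change, tumor minus normal, with its SE as bars, and the lower panel the number of the 29 tumors above the highest of the 29 normal livers, with the dashed line at the 0.967 tumors that chance gives. The red points, members that rose, lie from Rian to Mir409, and in the upper panel Meg3, Dlk1 and Dio3 lie near 0.

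**Figure D3:**
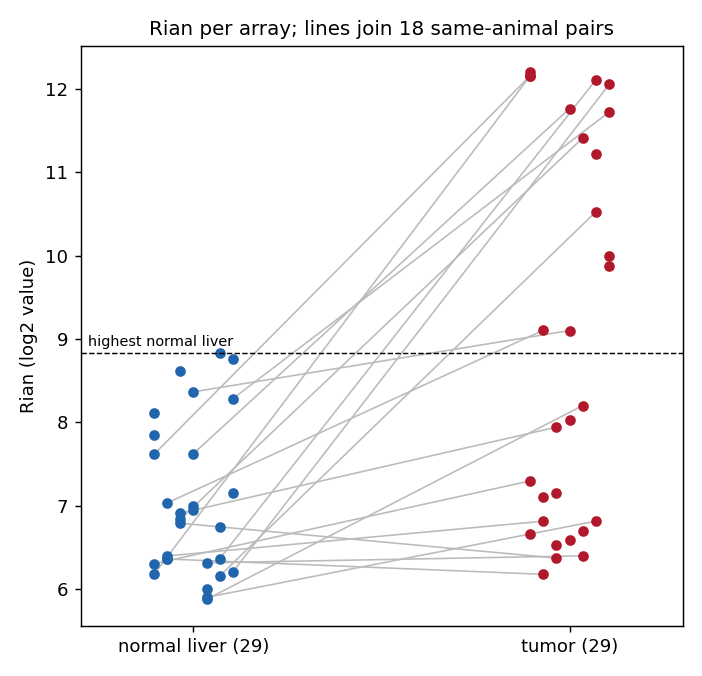
Log2 value of Rian (y axis) in each normal liver and each tumor, with grey lines joining the 18 same-animal pairs and a dashed line at the highest normal liver, 8.83. Points are spread sideways for display, and 14 tumors lie above the line, which is set by normal liver 27.

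The gender labels allowed males and females to be compared, although in 7 arrays of 4 animals the sex-chromosome transcripts went against the label. Xist, the RNA of the inactive X chromosome, was at least 11.7 in 22 arrays and at most 6.20 in the other 36, and the mean of the Y-linked genes Uty, Kdm5d and Eif2s3y parted the arrays the same way. Of the labelled males 4 arrays had the high Xist, and of the labelled females 3 arrays had the low one. They were normal livers 3, 14 and 15 and tumors 3, 14, 15 and 28. Comparisons between labels therefore mix the sexes, and counts of called genes are given also without those 7 arrays, a choice made after seeing the data.

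**Figure D4:**
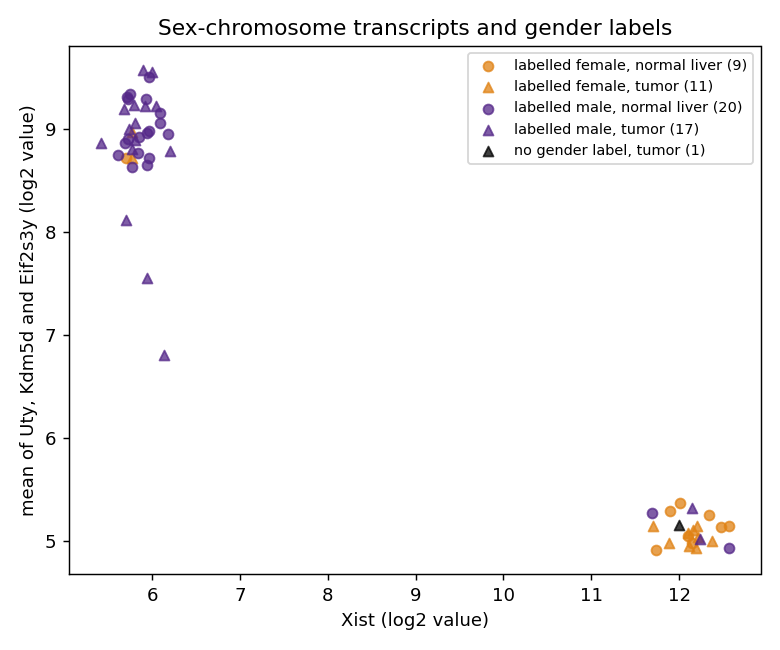
Xist (x axis, log2 value) against the mean of the Y-linked genes Uty, Kdm5d and Eif2s3y (y axis, log2 value) in each of the 58 arrays, with colors for the gender label, circles for normal liver and triangles for tumors. Arrays labelled male lie among the 22 arrays with high Xist in 4 cases, and 3 arrays labelled female lie among the other 36.

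In normal liver, Y-linked transcripts were higher in arrays labelled male and sulfotransferases of the Sult2a family were higher in arrays labelled female. Between 20 labelled males and 9 labelled females, 8 genes were higher in males and 3 in females. Besides Uty, Kdm5d and Eif2s3y, the spermatid genes Srsy (log2 difference 2.47, SE 0.48) and Sly (3.07, SE 0.61) were higher in males. Xist was higher in females (log2 difference, male minus female, -4.92, SE 0.79, limma adjusted p = 0.00060), as were Sult2a1 (-4.01, SE 0.75) and Sult2a2 (-3.69, SE 0.79), which add sulfate to steroids and bile acids. Without the 7 arrays, 11 genes were higher in males and 7 in females, and the difference for Sult2a1 was -5.05 (SE 0.66, adjusted p = 1.3e-06). Cyp2d9, a male-biased P450, had an adjusted p of 0.265 with all arrays and passed without the 7 (log2 difference 2.48, SE 0.51, adjusted p = 0.0123). Sult2a5 had an adjusted p of 0.153 with all arrays and passed without them, at -2.29 (SE 0.42, adjusted p = 0.0020). Both also passed with array weights, and Sult2a2 did not pass without the animal as a block (-3.58, adjusted p = 0.0791). Of 21 genes known to be higher in male liver 17 were higher in labelled males, 0 of them called over all genes and 7 adjusted over the list alone. Of 24 genes known to be higher in female liver none was higher in labelled males, with 2 called and 10 adjusted over the list alone. Cyp4a12a (2.13, SE 0.60, adjusted p = 0.632) and Cyp7b1 (1.21, SE 0.37, adjusted p = 1.00) of the male-biased list, and Hao2 (-1.41, SE 0.46, adjusted p = 1.00) of the female-biased list, did not pass over all genes, although Hao2 did with array weights (adjusted p = 0.0232). Leaving out the 7 arrays, 1 male-biased gene was called as higher in males and 2 female-biased genes as higher in females.

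In tumors, 3 genes passed both thresholds as higher in the 17 labelled males, which were Uty, Kdm5d and Eif2s3y, and 1, Xist, in the 11 labelled females. Without the 7 arrays 11 genes were higher in males and 1 in females. The difference for Sult2a1 was -2.18 (SE 0.72) with an adjusted p of 0.399, and -2.72 (SE 0.66, adjusted p = 0.174) without the 7 arrays. Of the 21 genes known to be higher in male liver, 11 were higher in labelled male tumors and 0 were called, over all genes or adjusted over the list alone. Of the 24 known to be higher in female liver, 7 were higher in labelled males, and 0 were called over all genes and 3 adjusted over the list alone. Leaving out the 7 arrays, 0 genes of either list were called over all genes.

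No gene passed over all genes in the test for a different tumor change in labelled males and females. The limma interaction called 0 genes of 22180 at an adjusted p under 0.05, with 1004 genes at an unadjusted p under 0.05. The test among the within-animal differences of the 18 pairs and that without the 7 arrays also called 0, the latter with 1130 genes at an unadjusted p under 0.05. Adjusted over the list alone, a choice made after seeing the data, 2 of the 24 female-biased genes and 0 of the 21 male-biased genes passed. These were Prom1 (male minus female tumor change 1.33, SE 0.43, adjusted p = 0.0395) and Rtn4r (0.39, SE 0.13, adjusted p = 0.0395), and both also passed without the 7 arrays (adjusted p = 0.0255 each). The tumor change passed both thresholds in 620 genes in labelled males and in 149 in labelled females. Of the 620, 618 had a change of the same sign in females, called or not, with a median of 0.639 times the change in males. These genes were chosen by their change in males, which lowers this ratio even where the changes are equal. The ratio among genes called in females was not computed. Without the 7 arrays the counts past both thresholds were 615 and 15, with 8 normal livers and 9 tumors of labelled females. These counts alone do not compare the sexes, since the groups differ in size. Tumors 1, 20, 24 and 25, all labelled female, also scored lowest of the tumors (0.007, 0.284, -0.043 and 0.535). On this score of the tissues the normal mean lies at 0 and the tumor mean at 1. No fit left these tumors out as a set.

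Some titles mark the animal as -/- or +/-, without naming a gene. From what is known of this line of work, the marks may stand for a disrupted Mmut gene that the vector is meant to replace, but the labels do not say so. Mmut had a log2 value of 9.34 ± 0.86 (SD, n = 4) in normal male livers marked -/- and 9.63 ± 0.42 (SD, n = 5) in those marked +/-, a difference that did not pass (log2 difference -0.29, SE 0.36, limma adjusted p = 0.916). Whether the probes lie in a deleted part is not known here, so Mmut does not check the marks. No gene passed an adjusted p under 0.05 in limma, with 1461 genes at an unadjusted p under 0.05. The lowest adjusted p was 0.450. The genes of smallest p fail the threshold. Those higher in -/- were Snora2b (log2 difference 1.02, SE 0.17), Tinag, Snora20, Vmn2r30 and Ptgr1, and those lower were Hhip (-1.13, SE 0.17), Aldh18a1, Egr1, Dnajc12 (-1.94, SE 0.35) and Atp1b3. Without normal liver 27, 3 genes were higher in -/-, among them Tinag, and without normal liver 7, 2 were lower, among them Hhip. One +/- liver, number 15, is among the arrays whose sex-chromosome transcripts went against the label. Of the 4 -/- livers, number 27 lay among the tumors in a score of the tissues (1.12, with the normal mean at 0 and the tumor mean at 1), and its animal title is also that of the +/- liver 26. Without both arrays of that title, 0 genes passed either way.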

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

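Tests of the sex-chromosome transcripts, of normal liver 27 and of the Y-linked genes were chosen after the values were seen, and the comparisons with other splits of the samples before. Tests of further Y-linked genes and of the tumor scores in 1 split were added later, with their limits set before their values were seen.

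Of 36 groups of 4 to 10 arrays tested for an array far from the rest, 7 had one, where chance gives about 1.8. In 6 of them it was normal liver 3, labelled female, among 9 such livers. Its Xist value was 5.70, with 11.73 the nearest of the others, and its Y-linked values were 8.85 for Uty, 8.05 for Kdm5d, 9.26 for Eif2s3y, 8.94 for Srsy and 7.44 for Sly. The other was Atp1b3 in normal liver 13 among the 5 livers marked +/-, at 9.98 against 10.83 for the nearest.

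Normal liver 3 is 1 of 7 arrays, from 4 animals, whose sex-chromosome transcripts went against the gender label. Mixed RNA of both sexes would raise Xist and the Y-linked genes together, and 0 of the 7 arrays had both above the range of arrays that lack them. In 3 of the 3 such animals with both tissues the arrays fell on the same side, a test of a wrong gender or animal number given for the whole animal, which is consistent with that explanation. Whether the label is wrong or the samples of animals were exchanged stays open, and no biological explanation was tested.

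Normal liver 27 lay among the tumors. On a score from the 200 genes that best parted the tissues in the other animals, with the normal mean at 0 and the tumor mean at 1, it had 1.12, while the next normal liver, 16, had 0.539 and the lower quartile of tumors was 0.925. A minor share of tumor cells would leave it lower than that. An exchange with tumor 28, whose title carries the same animal number with the other sex, would put that tumor among the normal livers, and its score was 0.967. Normal liver 27 and tumor 28 were each other's best match in plain correlation (0.9895), where the highest of any pair of arrays was 0.9897. Both had low Xist (5.73 and 5.77), although tumor 28 is labelled female. The possibility that both arrays hold RNA of the same tumor tissue stays open. With normal liver 27 set among the tumors, their deviations from the group means correlated at 0.578, above 95% of the 1653 pairs of arrays (0.352), but 3 other pairs correlated as highly, up to 0.751, and the limit for this test was set after the correlation was seen, in place of a first one under which any other pair as high would have excluded the explanation.

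Y-linked transcripts were low in tumors 11 and 26, both labelled male, with means of 7.55 and 6.80 against 9.0 ± 0.30 (SD) in the other arrays with low Xist. Female RNA in the sample would raise Xist, and the higher Xist value of the pair was 6.14, below the 6.20 reached by another array. A lower scale of the array is also ruled against, since the array median matched at most 4.10% of the shortfall. The other tumor of the animal of tumor 26 had a mean of 9.22. Loss of the Y chromosome in part of the tumor cells would lower further Y-linked genes too, and 6 that were not used to find these tumors were higher by at least 1 in the other arrays with low Xist than in those with high Xist. Their mean was 6.49 in tumor 11 and 7.76 in tumor 26, below the median of 7.97 of the other arrays with low Xist. But 0 of the 2 tumors lay below all of them (lowest 5.37). This test could hardly decide, since each of the 6 genes fell in some of those arrays close to its mean in arrays with high Xist. Sly, for example, went down to 3.95 against a mean of 3.75. Loss of the Y chromosome in part of the tumor cells therefore stays open, and no DNA was measured.

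Chance was set against each count with 100 splits. For tumors against normal liver, labels were swapped within pairs and shuffled among the other arrays, and 1 split, the real one with 439 genes, reached its count, with 94 the highest of the others. For labelled sex in normal liver 1 of 100 splits, the real one with 11 genes, did so, against at most 1 gene in another. Chance is thus an unlikely source of both counts, as far as 100 splits can tell. The 11 genes included the sex-chromosome transcripts Xist, Uty, Kdm5d, Eif2s3y, Srsy and Sly, which mostly correct labels must part. That count therefore does not test sex differences in other genes. In tumors 5 of 100 splits gave at least the 4 genes of the real labels, up to 23, so chance cannot be excluded for that count, although the 4 genes were Xist, Uty, Kdm5d and Eif2s3y, named for sex beforehand, and a count does not weigh which genes are called. For the interaction and for the -/- and +/- marks the real count was 0, which all 100 splits reached. The highest others were 1759 and 4 genes. The former came from 1 split, with at most 4 genes in any other split of the labels, and its cause is not known. An uneven spread of tumor scores over the groups of that split is argued against, since 75 of the 100 splits had as large a difference in score between the tumor changes of the labels, and what else its arrays share was not examined.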

How the results depend on the processing

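The fits without each animal, without the 7 arrays that go against the gender label, without tumor 9 and without the 3 arrays whose titles share the number of normal liver 27 were added after seeing the data. Counts of genes past both thresholds for tumors against normal liver stayed within 1.5 times of 229 and 210 under all 15 alternatives except one. With only the 11 normal livers and 11 tumors of animals without a pair, 114 genes were lower, and by adjusted p alone 1316 were higher and 656 lower, in fewer arrays. By adjusted p alone, the genes lower in tumors numbered 1804 with the fixed replicate block of the 18 pairs (fewer arrays), 1727 with arrays centred on the median, 1920 among brighter genes only (fewer genes tested) and 6169 with array weights, against 3166, and where no reason is named the cause was not tested. With array weights 46.4% of the called genes were higher and with centring 73.1%. With no replicate block the counts past both thresholds were 230 and 207, and 434 of the 439 genes were shared. Leaving out one animal at a time gave 217 to 262 higher and 188 to 238 lower genes past both thresholds, and 3636 to 4502 and 2785 to 4197 by adjusted p alone. For labelled sex, 3 genes were higher in males in normal liver among brighter genes only, against 8. Array weights gave 10 genes higher in females in normal liver, 2 in tumors and 310 with a tumor change in females. Without the 7 arrays these were 7, 1 and 15, and 11 genes were higher in males in tumors. For the -/- and +/- marks, leaving out one replicate gave 0 to 3 genes higher in -/- and 0 to 2 higher in +/-. The fixed replicate block changed no count for the interaction. Of the gene lists 10 rose and 10 fell, against 0 and 0 with the estimated correlation, and 6 rose among brighter genes only. The count of 14 tumors above all normal livers for Rian did not move under any alternative by over 1.5 times, while 11 other locus counts did and 118 did not. Over the refits of named genes for tumors against normal liver, 2630 kept their side of the threshold, 112 lost a call (77 of them in the arrays without a pair) and 23 gained one. None changed direction while called. With the fixed replicate block 13 of the named genes lost and 4 gained a call. The fit of arrays without a pair took the block correlation of all arrays. The cause of the other changes was not tested. Signal over background is not stated in the values, so for genes of low brightness it is not known which were detected.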

Other observations

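Apart from the fixed gene lists, the values in this part were picked after they were seen. Some regulators of body rhythms and of growth hormone signalling were called between tumors and normal liver, although neither list passed with all arrays. Of 14 circadian genes 2 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.226). Arntl rose 1.90-fold, while Hlf fell by 1.07 and Per3 by 0.98 on the log2 scale, each lower in 17 of 18 pairs. The hour at which tissue was taken is not given in the labels, and both tissues of an animal share it only if taken at the same time. Of 13 genes of the growth hormone and IGF axis 2 rose and 5 fell, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.133, and 0.0495 among the 18 pairs with the animal as a fixed block, there 0.525 with an estimated correlation). Igfbp2 fell by 1.69 (SE 0.20) and Lifr by 0.79, while Igfbp3 rose 1.89-fold. Among 24 genes higher in female liver 6 rose and 13 fell, or 7 and 14 adjusted over the list alone (camera adjusted p = 0.131, and 0.00440 among the 18 pairs with the animal as a fixed block, there 0.434 with an estimated correlation), with Prom1 up 3.23-fold and Cyp2c69 down by 2.51. Of 17 genes of the unfolded protein and integrated stress response 7 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.131), with Ddit3 up 2.33-fold and Herpud1 down by 0.59.

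Among 17 other imprinted genes 5 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.231). Phlda2 rose 1.87-fold, Grb10 1.63-fold, and Peg3 fell by 0.92. Of 16 genes often mutated in liver cancer 4 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.546), with Myc up 1.47-fold, Axin1 1.22-fold and Ccnd1 down by 0.90. Antigen presentation gave 6 rises among 12 genes, or 6 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.102, and 0.0409 with sex as a covariate, there 0.660 with an estimated correlation), with H2-Ab1 up 1.63-fold, a call lost without the 7 arrays (log2 change 0.67 against 0.70, adjusted p = 0.0529). In gluconeogenesis 2 rose and 3 fell of 8, the same adjusted over the list alone (camera adjusted p = 0.923), with Ppargc1a up 4.11-fold and Slc37a4 down by 0.92. The urea cycle gave 3 rises and 1 fall among 7 genes, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.147, and 0.000696 without tumor 9, there 0.224 with an estimated correlation). Asl rose 1.56-fold, and Otc fell by 0.94, a call lost without the 7 arrays (-0.84, adjusted p = 0.0870). Among 5 measured major urinary protein genes none was called, over all genes or adjusted over the list alone (camera adjusted p = 0.803). Mup3 was called as lower in the 18 pairs with the animal as a fixed block (log2 change -1.28, adjusted p = 0.0248), with array weights (-1.26, adjusted p = 0.0465) and without the 3 arrays whose titles share the number of normal liver 27 (-1.54, adjusted p = 0.0275). Mup20 was called as higher with array weights (1.09, adjusted p = 0.00228), with sex as a covariate (0.97, adjusted p = 0.0412) and without tumor 9 (1.01, adjusted p = 0.0227). The 3 Y-linked genes (camera adjusted p = 0.637) and Xist (log2 change 0.38, SE 0.72) were not called between tissues.

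At the Dlk1-Dio3 locus, Meg3 (log2 change -0.02, SE 0.08) and the 4 measured microRNA genes between it and Rian, Mir673 (-0.19, SE 0.08), Mir337 (-0.04, SE 0.08), Mir540 (-0.09, SE 0.06) and Mir665 (-0.05, SE 0.11), were not called with all arrays. With array weights Mir673 (adjusted p = 0.000652) and Mir540 (adjusted p = 0.0360) were called as lower, and Mir673 also with sex as a covariate (adjusted p = 0.0312). The measured members before Rian thus did not rise, Dlk1 and Meg3, which are not small RNAs, among them. Their tumors above the highest normal liver summed to 7, where chance gives 5.8. Whether the rise leaves out the whole start of the imprinted cluster stays open. Not all listed members were measured, probes of single small RNA genes can be unresponsive, and 6 members between Rian and Mir409 also did not rise. Of these 6, Mir758, Mir329 and Mir667 each had 5 tumors above the highest normal liver, all also above for Rian. Mir341 had 4, Mir299a 1 and Mir666 0. With the limit at the mean plus 3 SD, Mir329, Mir667 and Mir299a had 0. For each member before Rian, 0 of the tumors above were also above for Rian. Insertion sites of the vector were not measured.

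The tumor without a gender label, number 23, had a Xist value of 11.99 and a Y-linked mean of 5.15, within the range of the 22 arrays with high Xist. Tumors 24, 1, 20 and 25, all labelled female, had tumor scores of -0.043, 0.007, 0.284 and 0.535. These lay below the 0.539 of normal liver 16, the highest of the normal livers apart from number 27 at 1.12.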
